A study of Solanum virginianum with 24 samples.

How the data were processed

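Fruit of eggplant (Solanum melongena, per the series title, although the sample records give the organism as Solanum virginianum) was profiled on the Affymetrix tomato GeneChip on the day of anthesis (0 dpa) and 5, 10, 20 and 50 days later, with 3 arrays per stage that the labels call biological replicates. Per the labels, plants were kept in a glasshouse, flowers were pollinated by hand, and biotin-labelled cRNA made from total RNA was hybridised. Per the series design text, the authors made the values with RMA in GeneSpring GX 11.5, that is background correction, quantile normalisation and median polish, followed by a log2 transformation. RMA is also named in the submitters' processing notes, without a version.

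The deposited log2 values filled 24 columns for 15 distinct arrays. Per the labels, the 3 arrays of 0 dpa were normalised once with each later stage and so appear in 4 sets of 6 columns. Each 0 dpa column was taken as its deviation from the mean of the 3 0 dpa columns of its set. Between sets, these deviations had correlations of 0.62 to 0.71 across probe sets for the same replicate number, and -0.40 to -0.27 for different numbers. Taking off a mean of 3 pushes deviations of different arrays apart. The negative values are therefore no sign that replicates disagree in expression. In each set 100% of the table's 10209 probe sets had a median within 1e-05 of 0 over the 6 columns, so the authors' log2 values were centred per probe set and hold no signal level. Column medians lay between -0.0137 and 0.0116. The direction was taken as positive for higher expression and could not be checked against scanner values, which were not used here.

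The 108 control probe sets were left out of the tests, and 10101 remained. Gene symbols came from the platform annotation dated 2007: 909 probe sets had 1 symbol (207 of them a LOC number), 0 had several and 9192 had none. The symbols stand for 803 genes. For the 82 genes with several probe sets, the one with the highest mean over all columns stood for the gene, a choice that is arbitrary with centred values. Eggplant transcripts can differ from the tomato probes, which can lower a signal or let another family member contribute to it.

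Each stage was compared with the 0 dpa arrays of its own set with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, and p values were adjusted by Benjamini-Hochberg over the 10101 probe sets, with a threshold of 0.05. A count with a log2 fold change of at least 1, that is 2-fold, was kept beside it. For consecutive stages the values of each array were taken relative to the 0 dpa mean of its set and fitted over 12 arrays of the 4 later stages. This sets values across separately normalised tables, and the error of the 0 dpa mean, which comes from the same arrays, is not in those standard errors. The filters and settings used on low signals do not apply, because no signal level is left in the values. Plots were drawn with matplotlib 3.10.9.

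Lists were matched to the symbols. Those with at least 3 measured genes were tested with limma's camera (preset correlation 0.01, and again with an estimated correlation) and fry, with adjustment over the lists of a stage. The 16 tested lists were cell wall remodelling, ethylene synthesis and response, MADS-box and fruit regulators, photosynthesis, carotenoid and isoprenoid synthesis, phenylpropanoid and flavonoid synthesis, cell cycle and DNA replication, auxin, gibberellin with cytokinin and brassinosteroid, abscisic acid, sugar and starch metabolism, defence and wound response, heat shock and chaperones, pollen and anther markers, lipoxygenase and volatiles, and polyphenol oxidases and peroxidases. Histones, cytosolic ribosomal proteins, seed maturation markers, lipid transfer and cuticle, sterol and glycoalkaloid synthesis, aquaporins and reference genes had fewer than 3. LIN7 is in both the sugar and the pollen list. The seed maturation and pollen lists were meant as markers of other material that a whole fruit could hold.

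Named genes were taken by a rule. Per comparison with 0 dpa it took the 8 largest rises and the 8 largest falls among genes past the threshold whose arrays did not overlap, the 2 members of each list with the smallest p and the 2 with the largest change, and a fixed set of genes given whatever their values (EXP1, PCNA, Psy1, lin5, E8, CHS1, PG2, DFR, ACS2, TAGL1, TBG4, RIN and TDR4 were measured). Between consecutive stages it took the 5 largest rises and the 5 largest falls past the threshold, and for probe sets without a symbol at most the 2 largest rises and falls per comparison, given here by value. The groups, the tests across probe sets and of lists, the lists, the naming rule and all alternatives but 1 were fixed before the data were examined. Some tests of explanations and a criterion for genes called in opposite directions were chosen later and are named where they are given. Further list members, where named for comparison with another stage, were chosen after their values were seen.

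The steps were tested on simulated data with 200 changed probe sets among 10101. Changes of 0.5 on the log2 scale were recovered in 70.1%, 79.1%, 82.1% and 64.2% of cases for 5, 10, 20 and 50 dpa, and changes of 1 or 2 in 100%. False calls were 5.26%, 9.27%, 5.53% and 4.35% of all calls. For the comparison of 5 with 10 dpa the recovery at 0.5 was 68.7% and false calls were 4.79%. That simulation held no error of the 0 dpa means and none of the separate normalisation. Its share of false calls therefore cannot stand for that of the real comparison of consecutive stages. The shared calls of comparisons with the same controls were set beside simulated unchanged groups.

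The alternatives run were the methods' unpaired t-test, arrays centred on their median, a repeated quantile normalisation of the 6 arrays, probe sets open to cross-hybridisation left out, array weights, the replicate number as a block, all probe sets of a gene, and each array left out in turn. The repeated quantile normalisation ran on the values centred per probe set, where it evens out rises and falls by itself. The alternative added after seeing the data was a fit of all 15 arrays, each taken relative to the 0 dpa mean of its set.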

Results

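The series followed gene expression in eggplant fruit during its development and ripening. Fruit of 1 cultivar, named PPL in the labels, was taken from hand-pollinated flowers on the day of anthesis, 0 days post anthesis (dpa), and at 5, 10, 20 and 50 dpa. RNA was hybridised to a tomato GeneChip, so each value is the signal of eggplant transcripts on tomato probes and the gene symbols are those of tomato. Each stage had 3 arrays, which the labels call biological replicates, and the 3 arrays of 0 dpa served all 4 comparisons. Of the 10101 probe sets tested, 909 carried a gene symbol, for 803 genes, and the named results therefore describe 9% of the probe sets. The number of arrays limits the precision. Fold changes are on the log2 scale with standard errors after ±, and adjusted p values are from limma with Benjamini-Hochberg adjustment unless another test is named.

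**Figure D1:**
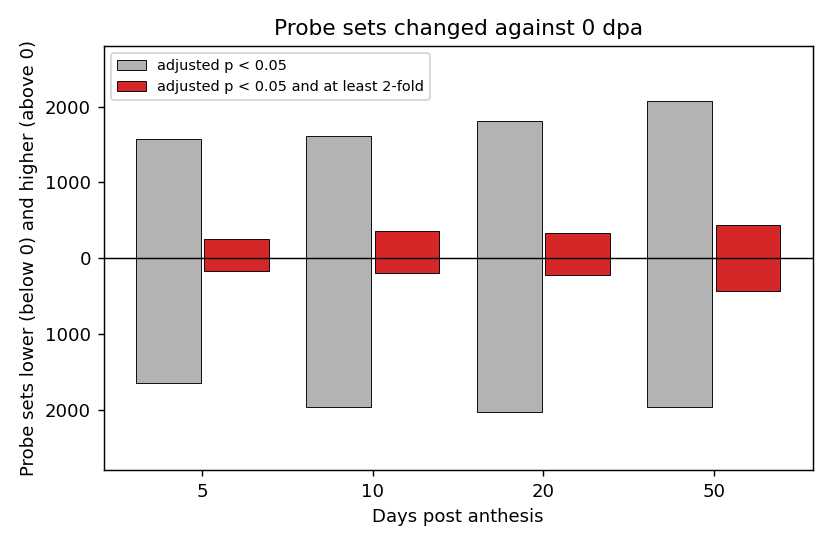
Number of probe sets (vertical axis) higher than at 0 dpa, above the zero line, and lower, below it, at each stage (horizontal axis, days post anthesis). Grey bars are all probe sets past an adjusted p of 0.05 in limma and red bars those also changed at least 2-fold, and the red bars reach 437 higher and 434 lower at 50 dpa.

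At 5 dpa, compared with 0 dpa to ask what changed in the days after pollination, transcripts of photosynthesis genes rose most among the named genes. PSBP, an extrinsic subunit of the oxygen-evolving complex, rose 10.6-fold (log2 3.41 ± 0.076, adjusted p = 1.04e-07). PsbQ, another extrinsic subunit, rose 5.87-fold (log2 2.55 ± 0.095, adjusted p = 1.16e-06), and the chlorophyll a/b-binding protein gene CAB6A rose 5.49-fold (log2 2.46 ± 0.082, adjusted p = 9.17e-07). CDKB2, a mitotic cyclin-dependent kinase gene, rose by 2.198 ± 0.085 and cel5, an endo-beta-1,4-glucanase gene, by 2.45 ± 0.14. The deepest fall among the named genes was that of fsm1, a gene for a small MYB-domain protein, which fell 9.09-fold (log2 -3.18 ± 0.18, adjusted p = 8.15e-06).

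Of the 8 photosynthesis genes measured, 7 rose and CAB5 did not pass (log2 0.36, adjusted p = 0.198), with a list median of 2.02. CAB4 (2.22 ± 0.082) and PSBO (1.82 ± 0.089) were among those that rose. The list stood above the other probe sets in limma's camera test (adjusted p = 6.13e-09; adjusted p = 0.0822 with an estimated correlation). On the same arrays the 5' probe set of the actin control stood higher against its 3' probe set than at 0 dpa, by 1.09 ± 0.061 on the log2 scale. Of 36 probe sets for bacterial transcripts used as labelling spikes, 32 were higher, with a median of 0.981.

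Ethylene genes fell more often than they rose. Of 35 measured, 14 fell and 2 rose, with a median of -0.27 (15 fell and 2 rose when adjusted over the list alone). Camera placed the list below the other probe sets (adjusted p = 0.000646; adjusted p = 0.0824 with an estimated correlation). EIL4 (-1.48 ± 0.092) and EIL1 (-1.29 ± 0.12), which encode EIN3-like transcription factors, and ACO4 (-1.17 ± 0.088), an ACC oxidase gene, were among those that fell. Of 13 cell cycle genes, 4 rose and 1 fell, including CYCD3, a D-type cyclin gene (1.16 ± 0.11), CycA2 (1.26 ± 0.25) and PCNA, the sliding clamp of DNA replication (0.72 ± 0.080). The cell wall list was divided, with 8 of 38 genes higher and 6 lower, among them the xyloglucan endotransglucosylase/hydrolase genes XTH3 (1.86 ± 0.19) and XTH1 (-1.14 ± 0.075). Auxin genes gave 5 rises among 7, the Aux/IAA genes IAA16 (1.55 ± 0.30) and IAA27 (0.92 ± 0.20) included. Of these 7 genes 0 passed in the methods' t-test (4 at an unadjusted p under 0.05), 3 passed without 0 dpa replicate 1, 0 dpa replicate 3 or 5 dpa replicate 1, and 2 without 0 dpa replicate 2. Of the ethylene genes 10 passed in the t-test.

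Carotenoid and isoprenoid genes gave 8 falls and 3 rises among 14. PDS, phytoene desaturase, fell (log2 -1.23 ± 0.12, adjusted p = 0.00018), and Psy1, phytoene synthase, had a fold change of -0.50 ± 0.12. CRTL-E-1, lycopene epsilon-cyclase, rose by 1.40 ± 0.097, as did DXS (1.03 ± 0.084), whose product opens the plastid isoprenoid pathway. Phenylpropanoid and flavonoid genes gave 3 rises and 3 falls among 9. The genes hqt, an acyltransferase gene of chlorogenic acid synthesis (1.10 ± 0.15), and CHS2 (0.85 ± 0.12) rose, while CHS1 (-0.73 ± 0.11) and DFR (-0.81 ± 0.25) fell. Lipoxygenase and volatile genes gave 2 rises and 5 falls among 11, with loxC at -0.75 ± 0.10 and AOC, allene oxide cyclase, at -0.71 ± 0.083. Among the fruit regulators 3 of 8 fell, including the MADS-box gene TAGL1 (-0.58 ± 0.076) and NAC1 (-0.65 ± 0.084), and RIN was at -0.11 ± 0.089 (adjusted p = 0.366). The sugar and starch list gave 3 rises and 3 falls among 20, with sus3, sucrose synthase, at 0.98 ± 0.10 and lin5, a cell wall invertase gene, at -0.70 ± 0.10. In the methods' t-test 7 carotenoid, 3 phenylpropanoid and 3 sugar and starch genes passed. Of the carotenoid genes 6 passed without 5 dpa replicate 1 or 0 dpa replicate 2 and 7 without 0 dpa replicate 3, of the lipoxygenase genes 4 without 0 dpa replicate 3, and of the sugar and starch genes 3 without 5 dpa replicate 3.

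Defence and wound genes gave 4 falls among 14 (5 when adjusted over the list alone), and abscisic acid genes 2 falls among 3. Heat shock genes gave 1 rise among 3 (vis1, a small heat shock protein gene, 0.79 ± 0.12), and polyphenol oxidases and peroxidases 2 rises among 7 (2 rises and 1 fall when adjusted over the list alone). In the gibberellin, cytokinin and brassinosteroid list 0 of 7 genes passed in limma, 0 at an unadjusted p under 0.05 and 0 in the methods' t-test. For the pollen and anther list these counts were 0, 0 and 0 of 5, with a median of -0.04 against a mean of 0.03 and an upward camera direction. Without 5 dpa replicate 2, RSI-1 of the former list (log2 -0.40, adjusted p = 0.0403, range over alternatives 0.0403 to 0.735) and PRK1 of the latter (0.52, 0.0371, range 0.0371 to 0.469) passed, as did 4 polyphenol oxidases and peroxidases. A fall of HSP21 passed without 5 dpa replicate 1 (0.0121, range 0.0121 to 0.522). Of the abscisic acid genes 1 passed without 0 dpa replicates 1 or 2 or any of the 5 dpa arrays, and 1 of these and 2 defence genes passed in the methods' t-test. The cell cycle and auxin lists came nearest to the threshold among lists not called by camera (adjusted p = 0.0804 for each). The cell cycle list passed without 5 dpa replicate 1 (0.0411, range over alternatives 0.0411 to 0.136) and the auxin list without 5 dpa replicate 3 (0.0178, range 0.0178 to 0.133). For the other lists named at this stage, the counts adjusted over the list alone were equal to those over all probe sets. Of the genes given whatever their values, those that did not pass were RIN (-0.11), EXP1 (-0.09), E8 (-0.09), PG2, a polygalacturonase gene (-0.15), ACS2 (0.19), TBG4 (0.05) and TDR4 (-0.03).

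Over all probe sets, 3230 passed an adjusted p of 0.05 in limma, 1578 higher and 1652 lower, and 432 changed at least 2-fold, 255 up and 177 down. The 3 and 3 arrays did not overlap for 46.8% of the probe sets, against 10% by chance. On the array of 5 dpa replicate 2, 53 probe sets, 1 of them with a gene symbol, lay more than 1 log2 unit below replicates 1 and 3. Against 0 dpa their medians were -1.13, -3.27 and -1.22 in replicates 1, 2 and 3, and 38 of them were called lower. Without that array 3090 probe sets passed, 1549 higher and 1541 lower. Under the methods' unpaired t-test the count was 2113, and Psy1, CycA2, IAA16 and IAA27 had adjusted p of 0.0763, 0.0805, 0.0783 and 0.089. These were the highest over their alternatives, whose lowest were 0.00588, 7.66e-05, 9.37e-05 and 0.00253. DFR did not pass without 0 dpa replicates 1 or 2 or 5 dpa replicates 1 or 2 (adjusted p = 0.0586, 0.092, 0.112 and 0.0761, range over alternatives 0.0314 to 0.187). NCED1, an abscisic acid synthesis gene (-0.42 ± 0.12), did not without 0 dpa replicates 1 or 2 or 5 dpa replicates 1, 2 or 3 (0.0593, 0.0736, 0.0629, 0.0631 and 0.0543, range 0.0194 to 0.11), nor did CHS1 in a fit of all 15 arrays (0.0995, range 0.00114 to 0.0995).

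At 10 dpa the photosynthesis transcripts stood further above 0 dpa, and an ACC oxidase transcript rose as well. PSBP rose by 4.14 ± 0.080 on the log2 scale (adjusted p = 5.76e-09) and PsbQ rose 13.7-fold (log2 3.77 ± 0.12, adjusted p = 1.06e-07). ACO5, which encodes an enzyme of the last step of ethylene synthesis, rose 10.5-fold (log2 3.40 ± 0.12, adjusted p = 1.37e-07). The endo-beta-1,4-glucanase gene Cel1 fell 6.42-fold (log2 -2.68 ± 0.085, adjusted p = 8.27e-08), and fsm1 fell 8.22-fold (log2 -3.04 ± 0.092, adjusted p = 6.14e-08).

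All 8 photosynthesis genes rose at least 2-fold, with a median of 2.94, including CAB6A (3.06 ± 0.077), PSBO (3.00 ± 0.11) and CAB4 (2.88 ± 0.084). In camera the adjusted p was 9.14e-11 (adjusted p = 0.179 with an estimated correlation). POR2, a protochlorophyllide oxidoreductase gene of chlorophyll synthesis, rose by 2.24 ± 0.084. Of the 14 carotenoid and isoprenoid genes, 3 rose and 5 fell (6 fell when adjusted over the list alone), with CRTL-E-1 at 2.15 ± 0.11, DXS at 1.72 ± 0.076 and Psy1 at -0.60 ± 0.11. That list had a median of -0.03, a mean of 0.06 and a downward camera direction. On these arrays 9 of the 36 probe sets of bacterial labelling spikes were lower than at 0 dpa and none higher (median -0.277). Outside these 36, the probe sets of the bioB, bioC and bioD controls were lower too, at -0.583 to -0.331, and all but 1 passed in limma. The 25S ribosomal RNA control was lower than at 0 dpa (-1.81 ± 0.27, adjusted p = 0.000871), and the 5' against 3' shift was 0.366 ± 0.17 for actin and 0.692 ± 0.13 for GAPDH.

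The ethylene list gave 16 falls and 4 rises among 35 (16 and 5 when adjusted over the list alone). Its camera adjusted p was 0.12, and 0.03 without 0 dpa replicate 2 (range over alternatives 0.03 to 0.219). ETR5, an ethylene receptor gene (-1.63 ± 0.097), and EIL4 (-1.59 ± 0.089) fell, as did ACO6, an ACC oxidase gene outside the list (-1.68 ± 0.19). The cell wall list gave 11 rises and 7 falls among 38 (12 and 8 when adjusted over the list alone), and XTH1 fell 4.31-fold (log2 -2.11 ± 0.076). Cell cycle genes gave 4 rises and 1 fall among 13, with CDKB2 at 1.27 ± 0.081, CYCD3 at 0.59 ± 0.082 and CycA2 at 0.84 ± 0.18, and PCNA at 0.19 did not pass. Of the cell cycle genes 3 passed in the methods' t-test. In the lipoxygenase list 3 genes rose and 2 fell among 11, with loxC at 1.25 ± 0.073 and AOC at -0.52 ± 0.079.

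The sugar and starch list gave 5 rises and 4 falls among 20 (7 and 4 when adjusted over the list alone), with sus3 at 1.34 ± 0.087, AGPL3, a subunit gene of ADP-glucose pyrophosphorylase, at 1.16 ± 0.17 and lin5 at -0.91 ± 0.13. Phenylpropanoid and flavonoid genes gave 3 rises and 3 falls among 9, with CHS2 at 1.04 ± 0.22, hqt at 0.76 ± 0.11, CHS1 at -0.54 ± 0.11 and DFR at -0.42 ± 0.13. Auxin genes gave 3 rises among 7, with IAA17 at 1.08 ± 0.17 and IAA16 at 0.98 ± 0.20. Fruit regulators gave 3 falls among 8 and defence and wound genes 5 falls among 14. The heat shock list gave 1 rise among 3 and polyphenol oxidases and peroxidases 1 rise and 1 fall among 7. HSP17-6, a small heat shock protein gene outside that heat shock list, fell by 0.70 on the log2 scale (-0.70) and passed. GA3ox1, a gibberellin 3-oxidase gene (-0.49 ± 0.14), was the single fall among the 7 hormone genes of its list. In the abscisic acid list 0 of 3 genes passed in limma, 1 at an unadjusted p under 0.05 and 0 in the methods' t-test. In the pollen and anther list these counts were 0, 0 and 0 of 5. TAS14 of the abscisic acid list passed with median centring, with quantile normalisation and without 0 dpa replicate 2 (adjusted p = 0.0437, 0.0402 and 0.0359, range over alternatives 0.0359 to 0.182). Without the last array 5 sugar and starch genes passed. GA3ox1 did not pass without 0 dpa replicates 1 or 2 or 10 dpa replicate 3. In the methods' t-test 3 phenylpropanoid and 1 auxin genes passed, and 0 heat shock genes and 0 genes of the GA3ox1 list (1 each at an unadjusted p under 0.05).

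Medians and means differed in sign for 3 further lists at 10 dpa, none of them past the camera test. They were the gibberellin, cytokinin and brassinosteroid list (0.05 and -0.04, camera up), the pollen and anther list (0.01 and -0.02, camera down), and the polyphenol oxidases and peroxidases (-0.07 and 0.05, camera up). For the lists with no second count given, the counts adjusted over the list alone were equal. PDF1B, a peptide deformylase gene, fell (log2 -1.55 ± 0.13, adjusted p = 3.45e-05) and CIP2b had a fold change of -1.53 ± 0.082. RIN (-0.13), TDR4 (0.11), TBG4 (-0.02), PG2 (-0.0055), ACS2 (0.18) and EXP1 (0.01) did not pass.

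In all, 3567 probe sets passed at 10 dpa, 1607 higher and 1960 lower, of which 544 changed at least 2-fold, 352 up and 192 down. Arrays did not overlap for 46.7% of the probe sets, against 10% by chance. Without single arrays some calls near the threshold ended. E8 (0.34 ± 0.10, adjusted p = 0.0287) did not pass without 0 dpa replicates 1 or 2 or 10 dpa replicate 2 (adjusted p = 0.0503, 0.0976 and 0.0988, range over alternatives 0.0202 to 0.0988). TAGL1 (-0.37 ± 0.12) did not without 10 dpa replicates 1 or 2 or 0 dpa replicates 2 or 3 (0.133, 0.107, 0.118 and 0.124, range 0.00492 to 0.151), nor did DFR without 0 dpa replicates 1 or 2 or 10 dpa replicates 1 or 3 (0.0652, 0.108, 0.117 and 0.1, range 0.0134 to 0.297). GA3ox1 did not without 0 dpa replicates 1 or 2 or 10 dpa replicate 3 (0.0699, 0.0684 and 0.0546, range 0.00603 to 0.122). In the methods' t-test CHS2, CycA2, IAA16 and vis1 (1.25 ± 0.27) had adjusted p of 0.0876, 0.0838, 0.0748 and 0.0948 (lowest over alternatives 0.000678, 0.00218, 0.000882 and 0.000294). In the fit of all 15 arrays CHS1 had 0.237 (range 0.00396 to 0.237). Quantile normalisation of the 6 arrays gave fold changes of 3.27 for PSBP, 3.05 for PsbQ, 2.75 for ACO5, 2.47 for CAB6A, -2.81 for XTH1, -3.55 for Cel1 and -3.86 for fsm1. That step ran on values centred per probe set, where the stage and 0 dpa distributions are near mirror images. It therefore evens out rises and falls by itself, and these values cannot show how far the genes depend on normalisation.

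By 20 dpa ACO5 was the named gene furthest above 0 dpa, with a rise of 82.1-fold (log2 6.36 ± 0.12, adjusted p = 1.7e-08). HSP17-6, a small heat shock protein gene, rose 15.4-fold (log2 3.94 ± 0.25, adjusted p = 7.89e-06), and MAN2, an endo-beta-mannanase gene of wall breakdown, rose 14-fold (log2 3.81 ± 0.27, adjusted p = 1.27e-05). PSBP remained above 0 dpa, at 13.4-fold (log2 3.74 ± 0.073, adjusted p = 1.7e-08). Cel1 fell 9.83-fold (log2 -3.30 ± 0.081, adjusted p = 3.59e-08) and the expansin gene EXPA4 5.38-fold (log2 -2.43 ± 0.094, adjusted p = 3.91e-07).

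All 8 photosynthesis genes rose, 6 of them at least 2-fold, with a median of 2.45, and PsbQ (2.62 ± 0.082), PSBO (2.50 ± 0.078) and CAB4 (2.45 ± 0.096) were among them. In camera the adjusted p was 9.95e-09 (adjusted p = 0.278 with an estimated correlation). The control shift of 5' against 3' probe sets was 0.521 ± 0.11 for actin and 0.954 ± 0.12 for GAPDH on these arrays. Of the 36 probe sets of bacterial labelling spikes, 8 were lower and none higher (median -0.168). Of 38 cell wall genes, 12 rose and 7 fell, including TBG4, a beta-galactosidase gene, which rose 4.11-fold (log2 2.04 ± 0.088, adjusted p = 8e-07), and XTH1 (-1.67 ± 0.078). Xegip, which encodes an inhibitor of xyloglucan-specific endoglucanase and lies outside the lists, rose by 2.72 ± 0.29. All 3 heat shock genes of the list rose, with vis1 at 1.60 ± 0.15 and HSP21 of the plastid at 0.79 ± 0.19, and 1 of them passed in the methods' t-test.

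The ethylene list gave 11 falls and 4 rises among 35 (12 and 4 when adjusted over the list alone), with ACO4 at -1.33 ± 0.11 and ETR5 at -1.11 ± 0.081 against the rise of ACO5. ACS2 did not pass (-0.06 ± 0.12, adjusted p = 0.733). Cell cycle genes gave 4 falls and 1 rise among 13: PCNA fell (log2 -0.98 ± 0.076, adjusted p = 2.59e-05) and CYCD3 had a fold change of -0.66 ± 0.076. Carotenoid and isoprenoid genes gave 4 rises and 6 falls among 14 (5 and 7 when adjusted over the list alone), with CrtR-b1, a beta-carotene hydroxylase gene, at 0.76 ± 0.075, DXS at 0.90 ± 0.098, PDS at -1.03 ± 0.15 and Psy1 at -0.86 ± 0.17. Auxin genes gave 3 rises among 7 (5 when adjusted over the list alone), with IAA16 at 1.25 ± 0.20 and IAA2 at 0.85 ± 0.16. Of them 5 passed without 20 dpa replicate 2 and 1 in the methods' t-test. Among the fruit regulators NOR, a NAC gene of ripening, rose by 0.59 ± 0.12, 2 of 8 fell, and RIN was at 0.01 (adjusted p = 0.941).

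Lipoxygenase and volatile genes gave 2 rises and 4 falls among 11, with loxC at 1.44 ± 0.072, ADH2, alcohol dehydrogenase, at 0.78 ± 0.17 and AOS, allene oxide synthase, at -0.76 ± 0.13. The list had a median of -0.14, a mean of 0.0031 and a downward camera direction. The sugar and starch list gave 3 rises and 5 falls among 20, with sus3 at 1.18 ± 0.083, FRK2, fructokinase, at 0.90 ± 0.078 and lin5 at -0.69 ± 0.13. It had a median of -0.03 against a mean of 0.0022 (camera down). CCR1, cinnamoyl-CoA reductase, rose by 1.32 ± 0.12 and CHS1 was at -0.74 ± 0.083 among 9 phenylpropanoid genes with 1 rise and 2 falls. Defence and wound genes gave 5 falls among 14, LAPA1, leucine aminopeptidase (-1.21 ± 0.14), included, and 3 without 0 dpa replicate 2, without 20 dpa replicate 2 or in the methods' t-test. The gibberellin, cytokinin and brassinosteroid list gave 2 rises and 2 falls among 7, and polyphenol oxidases and peroxidases 2 rises and 2 falls among 7. The abscisic acid list gave 0 of 3 past limma's test, 1 at an unadjusted p under 0.05 and 0 in the methods' t-test, with a median of 0.015 against a mean of -0.05 (camera down). For the pollen and anther list these counts were 0, 1 and 0 of 5. Without 0 dpa replicate 3 a fall of NCED1, of the abscisic acid list, passed (0.0246, range over alternatives 0.0246 to 0.248). The heat shock and auxin lists did not pass in camera (adjusted p = 0.0736 for each). Both passed without 0 dpa replicate 1 (0.0446 for each) and without 20 dpa replicate 2 (0.0457 and 0.031), with ranges over alternatives of 0.0446 to 0.111 and 0.031 to 0.134. Other lists at 20 dpa had equal counts when adjusted over the list alone.

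At 20 dpa 3830 probe sets passed, 1803 higher and 2027 lower, and 545 changed at least 2-fold, 325 up and 220 down. Arrays did not overlap for 49.4% of the probe sets, against 10% by chance. In the methods' t-test Psy1, NOR, IAA2, HSP21, ADH2 and 20ox-3, a gibberellin 20-oxidase gene (0.90 ± 0.23), had adjusted p of 0.0603, 0.0545, 0.0509, 0.0985, 0.0759 and 0.112 (lowest over alternatives 0.000133, 0.000415, 0.000875, 0.0015, 0.000881 and 0.0012). In the fit of all 15 arrays CHS1 had 0.0912 (range 0.000179 to 0.0912). DFR, at -0.57 ± 0.22 (adjusted p = 0.073), passed without 20 dpa replicate 1 (0.0146, range 0.0146 to 0.245). Quantile normalisation of the 6 arrays gave fold changes of 5.33 for ACO5, 3.09 for PSBP, -3.02 for EXPA4, -3.88 for fsm1 and -3.93 for Cel1, and its calls numbered 1899 higher and 1875 lower. As at 10 dpa, the step evens out rises and falls on values centred per probe set, so these values cannot show a dependence on normalisation.

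At 50 dpa the 3 deepest falls among named genes were those of 3 genes of the cell wall. XTH1 fell 38.9-fold (log2 -5.28 ± 0.086, adjusted p = 1.48e-08), Cel1 31.9-fold (log2 -4.996 ± 0.10, adjusted p = 2.51e-08) and EXPA4 25.2-fold (log2 -4.66 ± 0.10, adjusted p = 2.77e-08). The division genes CDKB2 (-3.92 ± 0.16), PCNA (-3.35 ± 0.091) and CYCD3 (-3.34 ± 0.071) fell between 10.2-fold and 15.1-fold. ACO5 rose 27.7-fold (log2 4.79 ± 0.17, adjusted p = 4.08e-07), HSP17-6 25.9-fold (log2 4.70 ± 0.24, adjusted p = 2.47e-06) and XET2, a xyloglucan endotransglycosylase gene, 19.4-fold (log2 4.28 ± 0.10, adjusted p = 5.28e-08).

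Of 38 cell wall genes, 16 fell and 6 rose, and 11 of the falls were at least 2-fold, with a median of -0.15. Camera placed the list below the other probe sets (adjusted p = 0.0154; adjusted p = 0.177 with an estimated correlation). TBG4 was at 0.59 ± 0.17. Of 13 cell cycle genes 6 fell and 3 rose, and the list did not pass (camera adjusted p = 0.0787), although it did without 0 dpa replicate 2 (0.0487) or 50 dpa replicate 2 (0.0481, range over alternatives 0.0481 to 0.117). The 25S ribosomal RNA control was higher on these arrays than at 0 dpa (1.04 ± 0.088, adjusted p = 4.15e-05), and the 17S control was not (-0.266 ± 0.094, adjusted p = 0.0547). Of the 36 probe sets of bacterial labelling spikes, 15 were lower and none higher (median -0.29). The actin control's 5' probe set stood higher against its 3' probe set by 0.386 ± 0.099, and the GAPDH control's by 0.315 ± 0.10.

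Among the 8 fruit regulators 5 rose and none fell, with RIN at 1.33 ± 0.18, NOR at 0.95 ± 0.17 and the MADS-box gene TDR6 at 0.80 ± 0.084. In camera the adjusted p was 0.0378 (adjusted p = 0.387 with an estimated correlation), and it was 0.0634 without 0 dpa replicate 1 (range over alternatives 0.0261 to 0.0634). The 3 genes of the heat shock list rose, with HSP21 at 1.12 ± 0.14, MTSHP of the mitochondrion at 0.78 ± 0.11 and vis1 at 0.74 ± 0.098 (camera adjusted p = 0.0378; adjusted p = 0.313 with an estimated correlation). Of the 8 photosynthesis genes 7 rose and PETE, plastocyanin, fell (log2 -0.35 ± 0.10, adjusted p = 0.0265), with a median of 1.49 (camera adjusted p = 0.000113; adjusted p = 0.155 with an estimated correlation). PSBP was at 2.42 ± 0.074, PsbQ at 2.18 ± 0.092 and CAB6A at 1.88 ± 0.074.

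The chalcone synthase genes CHS1 and CHS2, of the entry step to flavonoids, rose 4.47-fold (log2 2.16 ± 0.46, adjusted p = 0.00631) and 3.36-fold (log2 1.75 ± 0.21, adjusted p = 0.000314), while hqt was at -0.70 ± 0.13. Without 50 dpa replicate 3 the rise of CHS1 was 1.57 on the log2 scale. The 9 phenylpropanoid genes gave 3 rises and 1 fall, and 2 passed in the methods' t-test. DFR, of anthocyanin synthesis, did not pass (-0.86 ± 0.36, adjusted p = 0.0913). CrtR-b1 rose by 2.50 ± 0.10, Psy1 fell (log2 -0.80 ± 0.096, adjusted p = 0.00029) and CCD1A, a carotenoid cleavage dioxygenase gene, was at -0.79 ± 0.088. The 14 carotenoid and isoprenoid genes gave 3 rises and 7 falls (median -0.23, mean 0.05, camera down). TomloxE, a lipoxygenase gene outside the lists, rose by 3.06 ± 0.099. The lipoxygenase list gave 6 falls and 1 rise among 11, with AOC at -1.53 ± 0.081 and loxC at -0.62 ± 0.084.

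The ethylene list gave 8 rises and 6 falls among 35 (8 and 7 when adjusted over the list alone), with ACO4 at -1.91 ± 0.088. Its median of -0.03 stood against a mean of 0.03 (camera down). ACS2 did not pass (-0.16 ± 0.15, adjusted p = 0.432). Polyphenol oxidases and peroxidases gave 4 rises and 2 falls among 7, with the catalase genes cat1 at 0.96 ± 0.081 and CAT2 at -2.56 ± 0.10 (median 0.47, mean -0.09, camera up). The sugar and starch list gave 4 rises and 7 falls among 20, with sus3 at 1.18 ± 0.079, lin5 at -0.84 ± 0.10 and FRK2 at -0.64 ± 0.076. Defence and wound genes gave 4 rises and 1 fall among 14, with the chitinase gene CHI17 at 1.12 ± 0.12 and LAPA1 at -1.39 ± 0.091. Auxin genes gave 4 rises and 1 fall among 7, with IAA17 at 0.82 ± 0.14, and the abscisic acid list 2 rises and 1 fall among 3. In the methods' t-test 2 auxin genes and 0 abscisic acid genes passed (3 and 2 at an unadjusted p under 0.05). Of the auxin genes 2 passed without 0 dpa replicates 1 or 2 or 50 dpa replicate 2 and 3 without each of the other arrays. Of the abscisic acid genes none passed without 0 dpa replicate 1, and 1 without 0 dpa replicate 2 or 50 dpa replicates 1 or 3. The gibberellin, cytokinin and brassinosteroid list gave 1 fall among 7, that of the DELLA gene GAI (-0.48 ± 0.073), with a median of 0.017 and a mean of -0.06 (camera down). In the pollen and anther list 0 of 5 passed in limma, 0 at an unadjusted p under 0.05 and 0 in the methods' t-test. Other lists at 50 dpa had equal counts when adjusted over the list alone.

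Lists with fewer than 3 measured genes were not tested, and their members are given with their fold changes at 5, 10, 20 and 50 dpa. The histone gene H1 was at -0.33, -0.36, -0.86 and -0.79 ± 0.14, and the ribosomal protein gene RPL8 at 0.06, -0.04, -0.17 and -0.25 ± 0.071. The lipid transfer protein genes LE16 and TSW12 were at -0.27, 0.29, 0.06 and 0.51 ± 0.11 and at -0.52, -0.49, -1.14 and -1.44 ± 0.12. HMGR, an enzyme of sterol precursor synthesis, was at 0.14, -0.20, -1.50 and -0.77 ± 0.23. The aquaporin genes LePIP1 and pip1 were at 1.06, 1.12, -0.68 and -1.49 ± 0.19 and at 0.07, -0.07, 0.03 and 0.97 ± 0.12. The reference genes ACT and TUB, for actin and tubulin, were at -0.05, 0.08, 0.25 and 0.38 ± 0.11 and at 0.04, 0.52, 0.85 and 0.54 ± 0.075. Each value at 50 dpa passed in limma, and all but those of HMGR and ACT in the methods' t-test, and 0 seed maturation genes were among the named probe sets.

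At 50 dpa 4041 probe sets passed, 2076 higher and 1965 lower, and 871 changed at least 2-fold, 437 up and 434 down (447 and 448 without 0 dpa replicate 3, 442 and 449 without 50 dpa replicate 3). Arrays did not overlap for 50.8% of the probe sets, against 10% by chance. In the methods' t-test CHS1 had an adjusted p of 0.0772 (range over alternatives 6.07e-05 to 0.0772). TBG4 did not pass without 0 dpa replicates 1 or 2 (0.0695 and 0.07, range 0.00144 to 0.116), while DFR passed without 50 dpa replicate 3 (0.0431, range 0.0229 to 0.272). Of the 3 abscisic acid genes, TAS14 (0.47 ± 0.12) did not pass without 0 dpa replicates 1 or 3 (0.0611 and 0.0538, range 0.0086 to 0.0813). AO1 (0.29 ± 0.097) did not without 0 dpa replicates 1 or 2 or 50 dpa replicates 1, 2 or 3 (0.0919, 0.147, 0.0784, 0.132 and 0.0575, range 0.0389 to 0.147), nor did NCED1 (-0.62 ± 0.21) without 0 dpa replicates 1 or 2 or 50 dpa replicates 1 or 3 (0.125, 0.15, 0.138 and 0.111, range 0.0102 to 0.186).

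**Figure D2:**
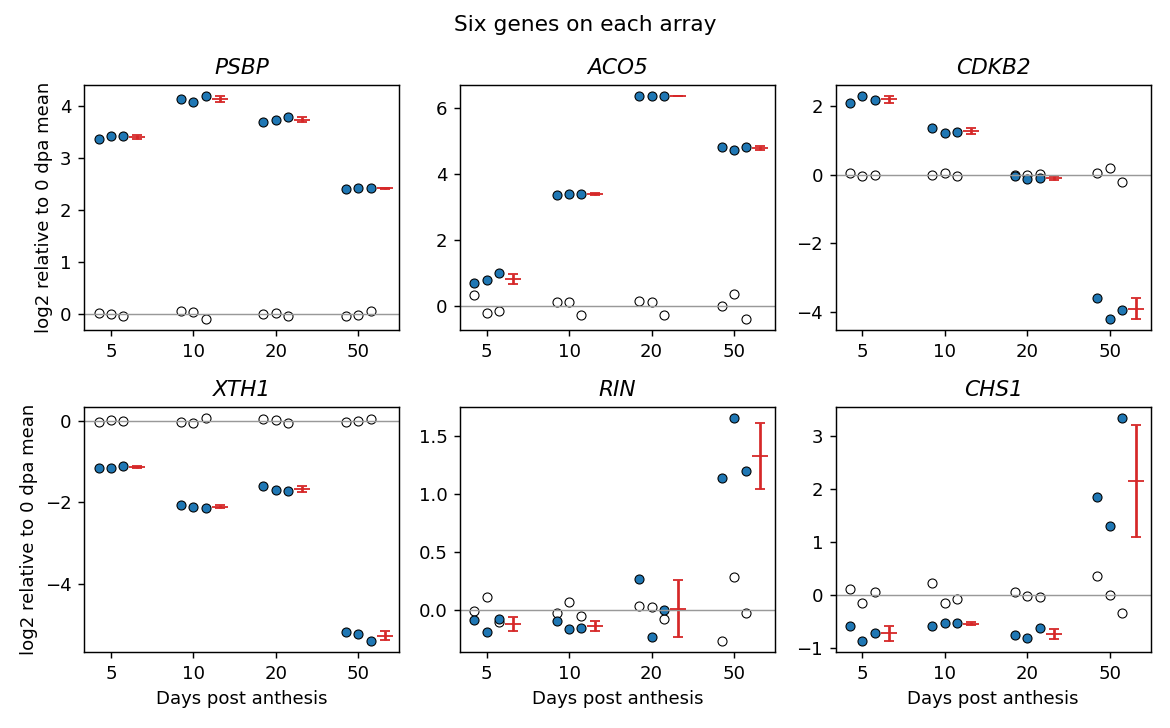
log2 values of PSBP, ACO5, CDKB2, XTH1, RIN and CHS1 (vertical axes) relative to the 0 dpa mean of the same normalised set, by stage (horizontal axes, days post anthesis, evenly spaced). Blue points are the 3 arrays of the stage, open points the 3 arrays of 0 dpa, and red bars the stage mean and SD of 3 arrays, and ACO5 reaches 6.36 at 20 dpa while XTH1 reaches -5.28 at 50 dpa.

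**Figure D3:**
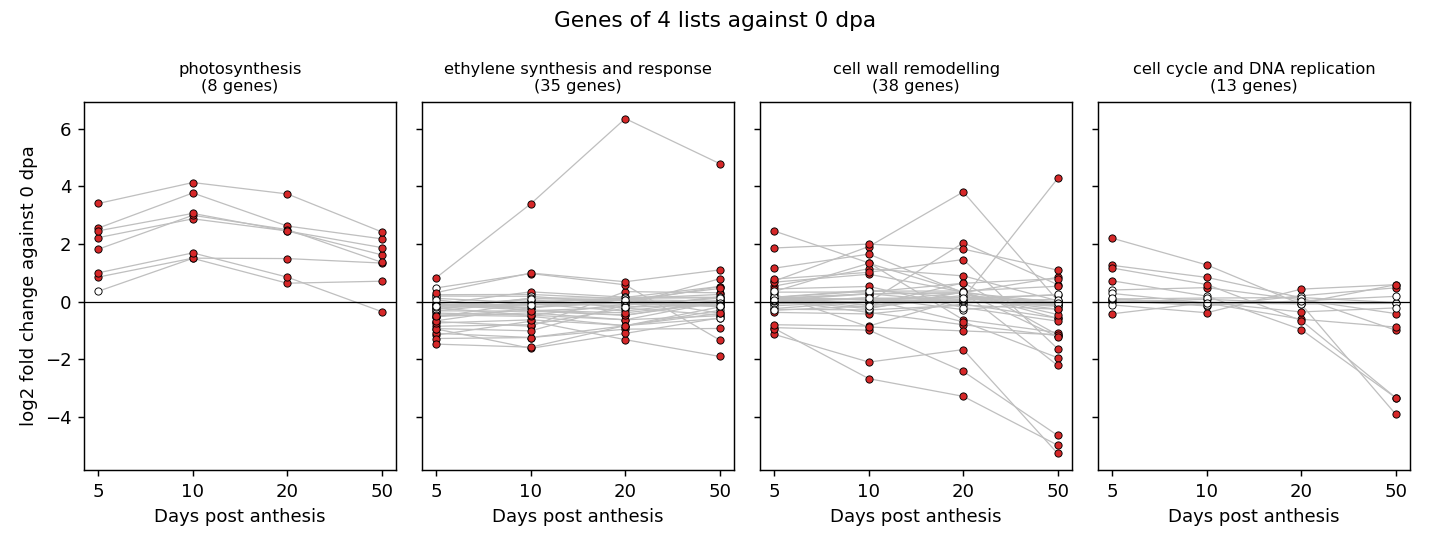
log2 fold change against 0 dpa (vertical axis) of each gene of 4 lists at 5, 10, 20 and 50 dpa (horizontal axes, evenly spaced), with grey lines joining the values of a gene. Red points passed an adjusted p of 0.05 in limma and open points did not, and all 8 photosynthesis genes lie above 0 at 10 dpa.

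Consecutive stages were compared on values taken relative to the 0 dpa mean of each stage's own set, since the sets were normalised separately. Between 5 and 10 dpa, ACO5 rose 5.92-fold (log2 2.56 ± 0.083, adjusted p = 2.63e-09), the lipoxygenase gene loxC 4.01-fold (log2 2.00 ± 0.081, adjusted p = 2.13e-08) and the expansin gene EXP5 3.02-fold (log2 1.60 ± 0.081, adjusted p = 1.52e-07). Cel1 fell 3.35-fold (log2 -1.74 ± 0.098, adjusted p = 2.59e-07). GABA-TP2 (1.47 ± 0.13), a GABA transaminase gene, and PsbQ (1.22 ± 0.077) rose, and RBOH1, an NADPH oxidase gene (-1.16 ± 0.15), XYL1 (-1.13 ± 0.11), CHI9 (-1.12 ± 0.11) and Prg1 (-1.11 ± 0.15) fell. All 8 photosynthesis genes rose further, with a median of 0.71 (camera adjusted p = 3.12e-10; adjusted p = 0.0918 with an estimated correlation). In the lipoxygenase list 2 genes rose and 1 fell among 11 (median 0.27, camera adjusted p = 0.0304; adjusted p = 0.176 with an estimated correlation). Its camera adjusted p was 0.0665 without 10 dpa replicate 2 (range over alternatives 0.0233 to 0.0665). The cell cycle list, with 4 falls and 1 rise among 13 (5 and 1 when adjusted over the list alone), had a camera adjusted p of 0.0737, and 0.0354 without 5 dpa replicate 1 (range 0.0354 to 0.218). In all, 2269 probe sets passed, 1039 up and 1230 down, and 180 changed at least 2-fold.

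Between 10 and 20 dpa, HSP17-6 rose 25-fold (log2 4.64 ± 0.081, adjusted p = 4.78e-13) and ACO5 7.79-fold (log2 2.96 ± 0.083, adjusted p = 7.12e-11). Xegip (2.35 ± 0.092), TBG4 (2.05 ± 0.14) and MAN2 (1.899 ± 0.15) rose. The cell wall list gave 9 rises and 12 falls among 38 (10 and 12 when adjusted over the list alone), with a median of 0.0092 and a downward camera direction (adjusted p = 0.759). The endoglucanase gene cel5 fell 3.94-fold (log2 -1.98 ± 0.13, adjusted p = 1.32e-07), and LePIP1 (-1.80 ± 0.19), ST2 (-1.61 ± 0.10), CRTL-E-1 (-1.58 ± 0.16) and GS2, a plastid glutamine synthetase gene (-1.52 ± 0.078), fell. Photosynthesis genes gave 7 falls among 8, with a median of -0.56 (camera adjusted p = 0.000467; adjusted p = 0.601 with an estimated correlation). In all, 3465 probe sets passed, 1713 up and 1752 down, and 462 changed at least 2-fold. The larger side turned without 10 dpa replicate 1 (1489 up and 1478 down), 10 dpa replicate 2 (1472 and 1454) or 20 dpa replicate 3 (1563 and 1554).

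Between 20 and 50 dpa, XET2 rose 18-fold (log2 4.17 ± 0.12, adjusted p = 2.44e-11), TomloxE 9.93-fold (log2 3.31 ± 0.10, adjusted p = 5.02e-11) and CHS1 7.45-fold (log2 2.90 ± 0.35, adjusted p = 2.67e-05), and CHS1 by 2.31 on the log2 scale without 50 dpa replicate 3. CDKB2 fell 14.1-fold (log2 -3.82 ± 0.12, adjusted p = 8.03e-11), MAN2 13.7-fold (log2 -3.78 ± 0.15, adjusted p = 4.58e-10) and XTH1 12.2-fold (log2 -3.61 ± 0.080, adjusted p = 6.13e-12). CrtR-b1 (1.74 ± 0.069) and NML2 (1.505 ± 0.13) rose, and TPRP-F1 (-3.55 ± 0.10) and the endoglucanase gene CEL8 (-3.10 ± 0.086) fell. Of 38 cell wall genes 20 fell and 3 rose, with a median of -0.39 (camera adjusted p = 3.54e-07; adjusted p = 0.00285 with an estimated correlation). Photosynthesis genes gave 6 falls among 8 (median -0.70, camera adjusted p = 2.38e-05; adjusted p = 0.168 with an estimated correlation), and fruit regulators 5 rises among 8 (median 0.45, camera adjusted p = 0.0117; adjusted p = 0.106 with an estimated correlation). Cell cycle genes gave 5 falls and 2 rises among 13 (median -0.17, camera adjusted p = 0.0471; adjusted p = 0.198 with an estimated correlation). Its camera adjusted p was 0.0516 with arrays centred on their median and 0.0644, 0.086 and 0.0642 without 20 dpa replicate 3, 50 dpa replicate 1 and 0 dpa replicate 3 (range over alternatives 0.0263 to 0.086). When adjusted over the list alone, 22 cell wall genes and 6 cell cycle genes fell, and the other counts given for these stages were equal. In all, 3510 probe sets passed, 1949 up and 1561 down, and 595 changed at least 2-fold.

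Calls shared between stages were counted among the comparisons with 0 dpa. At 5 and 10 dpa, 948 probe sets were higher and 1104 lower at both stages and 50 were called in opposite directions, where independent lists of these sizes would share 251 and 321. At 20 and 50 dpa the counts were 1061, 1151 and 265, against 371 and 394 for independent lists. At 5 and 50 dpa they were 500, 597 and 787, against 324 and 321. For 10 and 20 dpa they were 835, 1018 and 307 (independent lists, 287 and 393), for 5 and 20 dpa 753, 865 and 331 (282 and 332), and for 10 and 50 dpa 560, 739 and 833 (330 and 381). The numbers for independent lists are for the same direction only. None was worked out for opposite calls, so the size of an opposite count does not by itself show an excess. Among probe sets changed at least 2-fold at both stages, 163 were higher, 97 lower and 0 opposite at 5 and 10 dpa, against 8.89 and 3.36 for independent lists. For 20 and 50 dpa these counts were 149, 136 and 17 (14.1 and 9.45), for 5 and 50 dpa 60, 62 and 61 (11 and 7.6), and for 10 and 20 dpa 152, 90 and 4 (11.3 and 4.18). For 5 and 20 dpa they were 105, 75 and 8 (8.2 and 3.86), and for 10 and 50 dpa 83, 69 and 64 (15.2 and 8.25). Over probe sets, which are not independent replicates, fold changes at 5 and 10 dpa had a correlation of 0.75 and a covariance of 0.193, where simulated unchanged groups against the same 0 dpa arrays gave 0.47 and 0.0061. Those at 5 and 50 dpa had 0.13 and 0.0428, where simulation gave 0.46 and 0.0065. For 5 and 20 dpa the values were 0.5 and 0.137 (simulation, 0.47 and 0.0062), and for 10 and 20 dpa 0.61 and 0.18 (0.48 and 0.0058). For 20 and 50 dpa they were 0.59 and 0.228 (0.48 and 0.0062), and for 10 and 50 dpa 0.2 and 0.073 (0.48 and 0.006). The simulated correlations come from the shared controls alone, with the same control noise in each set and no changed probe sets. They are no baseline for fold changes that hold stage differences. A correlation below them, as at 5 and 50 dpa, does not show less likeness than between unchanged groups. Simulated unchanged groups shared 0 calls in limma in any pair of stages. With no changed probe sets in the simulation, hardly any calls can arise there. That count therefore cannot show how much overlap the shared controls add among changed probe sets. The 3 arrays of 0 dpa cannot be parted into sets of 2, so part of the excess may come from the shared controls.

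Among the 64 list results against 0 dpa, 8 passed in camera with its preset correlation and 0 with an estimated correlation. A test of whether a list's genes moved one way on balance (fry) passed for 36. Its mixed form, for change in either direction, passed for 54, and neither compares a list with other genes. The genes IAA7, adc1 and CRY1A at 5 dpa, ats1, LOC543989 and H1 at 20 dpa, and IAA7 at 50 dpa had probe sets called in opposite directions. Among probe sets without a symbol, the largest rises were 4.33 ± 0.093 at 5 dpa, 5.39 ± 0.081 at 10 dpa, 7.59 ± 0.15 at 20 dpa and 6.04 ± 0.12 at 50 dpa, and the deepest fall was -8.48 ± 0.30 at 50 dpa.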

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

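The tests chosen only after the result was seen were the share of low probe sets with a gene symbol (its criterion was also tightened after its value was seen), both tests of the 5' against 3' shift, and the comparison of ACO5 with ACO4 and ACO6.

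Lists whose change differed between consecutive stages are given with the median difference of their members. The photosynthesis list differed by 0.71 from 5 to 10 dpa (camera adjusted p = 3.12e-10; adjusted p = 0.0918 with an estimated correlation), by -0.56 from 10 to 20 dpa (0.000467; adjusted p = 0.601 with an estimated correlation) and by -0.70 from 20 to 50 dpa (2.38e-05; adjusted p = 0.168 with an estimated correlation). The lipoxygenase and volatile list differed by 0.27 from 5 to 10 dpa (camera adjusted p = 0.0304; adjusted p = 0.176 with an estimated correlation). From 20 to 50 dpa the cell wall list differed by -0.39 (camera adjusted p = 3.54e-07; adjusted p = 0.00285 with an estimated correlation). The fruit regulators differed by 0.45 (0.0117; adjusted p = 0.106 with an estimated correlation) and the cell cycle list by -0.17 (0.0471; adjusted p = 0.198 with an estimated correlation).

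Genes that the naming rule took at either stage, and that passed in opposite directions at consecutive stages with a tested difference, are given with that difference; this criterion was set after the values were seen. From 5 to 10 dpa loxC differed by 2.00 ± 0.081. From 10 to 20 dpa the differences were 0.90 ± 0.13 for GA3ox1, -1.14 ± 0.12 for AOS, -1.80 ± 0.19 for LePIP1, -1.98 ± 0.13 for cel5, -1.25 ± 0.085 for CYCD3, 4.64 ± 0.081 for HSP17-6, -1.20 ± 0.14 for hqt and 1.59 ± 0.13 for CCR1. From 20 to 50 dpa they were -1.54 ± 0.066 for FRK2, -3.55 ± 0.10 for TPRP-F1, -1.38 ± 0.089 for DXS, 2.90 ± 0.35 for CHS1 (2.31 without 50 dpa replicate 3), -1.71 ± 0.31 for IAA16, -2.06 ± 0.081 for loxC, -3.005 ± 0.089 for CAT2, 0.91 ± 0.089 for NAC1 and -3.10 ± 0.086 for CEL8. The adjusted p values of these 18 differences lay between 4.78e-13 and 0.000788 in limma.

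Control probe sets, which enter no comparison, also differed from 0 dpa. The 36 probe sets of bacterial labelling spikes had median fold changes of 0.981, -0.277, -0.168 and -0.29 at 5, 10, 20 and 50 dpa, with 32 higher at 5 dpa and 9, 8 and 15 lower at the later stages. Of the 108 controls 43, 47, 16 and 24 were called. The 25S ribosomal RNA control had fold changes of -0.71, -1.81, 0.00811 and 1.04 at 5, 10, 20 and 50 dpa, and all but that at 20 dpa passed in limma. The 17S ribosomal RNA control was at -0.407, -1.04, 0.0819 and -0.266, and only its value at 10 dpa passed. The actin control's 5' against 3' shift was 1.09, 0.366, 0.521 and 0.386 at 5, 10, 20 and 50 dpa.

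On the array of 5 dpa replicate 2, 53 probe sets lay more than 1 log2 unit below close values of replicates 1 and 3, with a median difference of -1.80 and a lowest of -5.22, against 0 to 3 such probe sets on the other arrays. Lower transcript levels of photosynthesis genes in that sample are argued against by a median difference of 0.0376 over that list. Less ribosomal or other untailed RNA on the array stays open, since the 25S control differed by -0.834 there, between the bounds set for and against it. A general loss of signal stays open too, because the test used cannot decide it. Of the 53, 1 has a symbol, and the shares with and without one (0.11% and 0.566%) gave a two-sided Fisher exact p of 0.087. The 53 were among 10101 probe sets, and whether they have a symbol has no direct bearing on signal. Their medians against 0 dpa were -1.13 and -1.22 in replicates 1 and 3 and -3.27 in replicate 2, and 48 of the 53 passed without that array, so the part of the fall found in all 3 arrays stays open as an effect of the stage, untested.

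The 5' probe sets of actin and GAPDH stood higher against their 3' probe sets at each later stage than at 0 dpa. More fragmented plant RNA in the 0 dpa samples is one candidate explanation. The lowest shift over actin, GAPDH and EF1a was 0.15 ± 0.13, above 0 in each of the 12 values. Other plant controls were not in this test. The GlutTrans 5' probe set also stood higher against its 3' probe set at each stage, and that of Ubiquitin at all but 10 dpa. For PhyB2 the 5' probe set was at 0.0636, -0.11, -0.0549 and -0.137 at 5, 10, 20 and 50 dpa. Its 3' probe set was at 0.136, 0.136, 0.0213 and 0.15, higher at each stage, although none of these values passed in limma. Shorter labelled products for every RNA stay open on the mean shift of 4 bacterial transcripts. That mean was above 0 by more than its SE at 5 and 20 dpa (0.326 ± 0.12 and 0.274 ± 0.091) and by less at 10 and 50 dpa (0.0233 ± 0.10 and 0.0641 ± 0.093). It does not speak for every RNA, since its members differed in direction at 5 dpa. There dap and lys were at 0.933 ± 0.27 and 1.12 ± 0.21, and phe and thr at -0.459 ± 0.34 and -0.288 ± 0.12. The shift of actin and GAPDH goes with the stage in every comparison, so an effect of RNA quality and one of development cannot be told apart for these transcripts.

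ACO5 rose at each later stage, to 6.36 ± 0.12 at 20 dpa. Signal of ACO4 or ACO6 on its probe set is argued against, since the higher of their fold changes at 20 dpa was -1.326. A single array as the source is argued against by the smallest value with 1 array left out, 6.224. Cross-hybridisation of a family member without a symbol was not tested and stays open, as does a true rise of the transcript, which the stages of the design could account for.

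With 3 arrays against 3 there are 10 splits, which are too few for a share under 0.05. The real split was the 1 with as many probe sets in each comparison. Each other split puts arrays of both stages on both sides, so the stage difference itself adds to the spread and lowers the count. The counts of the other splits are therefore not a level without a stage effect. The real counts were 3230, 3567, 3830 and 4041 at 5, 10, 20 and 50 dpa and 432, 544, 545 and 871 at 2-fold, and the highest other split gave 0 in limma for each. Between consecutive stages the real counts were 2269, 3465 and 3510, and the highest other split gave 1, 0 and 0.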

How the results depend on the processing

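The alternative added only after the data were seen was the fit of all 15 arrays; the others were planned. Under the methods' unpaired t-test the count at 5 dpa was 2113 (1029 up and 1084 down, 1976 shared with the 3230), and the cause was not tested; at 10, 20 and 50 dpa it gave 2650, 2900 and 3176, and at 2-fold 379, 527, 527 and 855. All other counts of changed probe sets stayed within 1.5 times the reported ones under the alternatives run, while shared calls were fewer at 2-fold in all 6 pairs of stages. Counts within lists moved by more in places under the t-test, without single arrays and with all probe sets of each gene. Many of these moves, though not all, are given with the lists. The 7 auxin genes have 14 probe sets. With all of them the auxin counts were 8 up and 1 down at 5 dpa, 6 and 1 at 10, 5 and 2 at 20, and 6 and 4 at 50 dpa. The auxin counts given above thus depend on the probe set that stands for a gene. None of the called genes and lists changed sign, but the larger of the higher and lower counts did in places: 1549 and 1541 at 5 dpa without 5 dpa replicate 2, 1252 and 1252 without 0 dpa replicate 1, and, after quantile normalisation, 1899 and 1875 at 20 dpa and 1980 and 2035 at 50 dpa. Quantile normalisation ran on values centred per probe set, where it evens out higher and lower counts by itself. Its turns are therefore no test of the reported balance. At 2-fold at 50 dpa the counts were 429 and 438 with median centring, 431 and 436 with quantile normalisation, 412 and 415 without probe sets open to cross-hybridisation, and 447 and 448 or 442 and 449 without 0 or 50 dpa replicate 3. Between 10 and 20 dpa the larger side turned without 10 dpa replicates 1 (1489 and 1478) or 2 (1472 and 1454) or 20 dpa replicate 3 (1563 and 1554). Quantile normalisation gave 3294, 3461, 3774 and 4015, with 1645 up and 1649 down at 5 dpa and 1717 and 1744 at 10 dpa, and at 2-fold 228 up and 218 down at 5 dpa, 301 and 248 at 10 dpa and 293 and 276 at 20 dpa. All splits under quantile normalisation share the limit given above, since that step evens out the sides of centred values. Median centring gave 1614 up and 1618 down at 5 dpa, 1685 and 1848 at 10, 1885 and 1925 at 20 and 2025 and 2019 at 50 dpa. Between consecutive stages it gave 1098 and 1172, 1714 and 1757, and 1749 and 1663, where the reported split from 20 to 50 dpa was 1949 and 1561. The fit of 15 arrays gave 3674, 3518, 3980 and 4258, and 2582, 3692 and 3741 between consecutive stages. Leaving out 1 array at a time gave 2453 to 3090 at 5 dpa, 2939 to 3122 at 10, 3183 to 3472 at 20 and 3420 to 3657 at 50 dpa, at 2-fold 411 to 459, 543 to 555, 549 to 556 and 870 to 895, and between consecutive stages 1660 to 2399, 2904 to 3596 and 2996 to 3582.

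Replicate numbers gave little sign of pairing the samples: deviations of same-numbered arrays had correlations of -0.017 to 0.10, and those of other pairs -0.11 to 0.051. In each stage 2 of 3 arrays correlated best with their own number, so a weak pairing stays open. With the replicate block the counts were 3073, 3403, 3725 and 3831, and 2220, 3447 and 3490 between consecutive stages. Of 238 named gene results, 183 passed; 29 no longer did under the t-test, 11 with some array left out, 2 with the block and 8 under other settings. Those that no longer passed with the block were E8 at 10 dpa (adjusted p = 0.0636, range 0.0202 to 0.0988) and AO1 at 50 dpa (0.0908, range 0.0389 to 0.147). Of 64 list results 8 changed their side of the threshold under some alternative, and 1 call was lost. The auxin list, not called, had an adjusted p of 0.0306 at 5 dpa and 0.0439 at 10 dpa with all probe sets of each gene, and 0.0396 at 20 dpa with the block (ranges over alternatives 0.0178 to 0.133, 0.0439 to 0.252 and 0.031 to 0.134).

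Filters on dim probe sets, a mean-variance trend in eBayes, and a joint quantile normalisation of all 15 arrays were planned and not run, because the centred values hold no signal level. For the same reason signal over background is unknown, and which probe sets lie near it cannot be said.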

Other observations

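POR2 at 10 dpa, ADC at 50 dpa and MKK4 at 5 dpa were taken by the naming rule, and the other values in this part were chosen after they were seen. All are from limma's comparison with 0 dpa. POR2, a gene of chlorophyll synthesis, was at 1.38 ± 0.088, 2.24 ± 0.084, 1.62 ± 0.088 and 1.29 ± 0.098 at 5, 10, 20 and 50 dpa, and GSA-AT, glutamate-1-semialdehyde aminotransferase, at 0.82 ± 0.090, 1.62 ± 0.13, 0.85 ± 0.096 and 0.54 ± 0.077, and each value passed. GS2, plastid glutamine synthetase, rose at 5, 10 and 20 dpa (1.34 ± 0.095, 1.98 ± 0.10 and 0.46 ± 0.11) and fell at 50 dpa (-1.83 ± 0.082, adjusted p = 1.22e-06).

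ADC, arginine decarboxylase, was at -0.14 ± 0.079 and -0.06 ± 0.073 at 5 and 10 dpa, which did not pass, and fell (log2 -1.51 ± 0.084, adjusted p = 3.41e-06) at 20 dpa and (log2 -3.32 ± 0.090, adjusted p = 1.01e-07) at 50 dpa. ODC, ornithine decarboxylase, fell at each stage (-1.17 ± 0.090, -0.57 ± 0.087, -1.48 ± 0.082 and -1.21 ± 0.077). MKK3, a MAP kinase kinase gene, rose at 5 and 10 dpa (1.58 ± 0.10 and 1.06 ± 0.11), was at 0.26 at 20 dpa (adjusted p = 0.0943) and fell at 50 dpa (-2.17 ± 0.21). MKK4 fell at each stage (-1.35 ± 0.082, -1.43 ± 0.075, -1.17 ± 0.075 and -1.36 ± 0.074), while MPK3 rose at 20 and 50 dpa (0.53 ± 0.085 and 1.49 ± 0.099).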
